A study of Mus musculus with 34 samples.

How the data were processed

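RNA sequencing was run on bone marrow-derived macrophages of mice aged 10 to 14 weeks, per the labels. Marrow cells were grown for 6 days with 10 ng/ml M-CSF, rested for 24 h and treated for 24 h with 200 mg/dL LDL or vehicle. The labels name both depletion of ribosomal RNA and selection of polyadenylated RNA, and do not give the sex of the mice. The main set held 24 libraries, 3 for each of 8 groups formed by genotype (WT, Dnmt3aKO, Tet2KO, Jak2VF) and treatment. A further 10 libraries, named batch 1 in the labels, held WT and Tet2KO, and were fitted apart because no library of the main set was part of them. All 34 libraries were used, and 0 columns of values were left out.

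The deposited tables hold counts, 1 whole number per gene and library, for 52550 genes in the main set and 25498 in batch 1. The deposited file names call these counts normalized, but totals differ by up to 1.82-fold within the main set and 2.93-fold within batch 1, the medians follow the totals, and values of 1, 2, 3 and upward occur without gaps. They were read as counts that were not scaled between libraries. Reads were aligned to mm10 per the submitters' processing notes, and the aligner, the counting tool and the gene annotation are not given in the sources used here. Gene names came from the table where it gave one (24183 genes in the main set, 17149 in batch 1) and otherwise from the Ensembl annotation of GRCm38, after which 52457 and 25418 had a name. In the main set 5771 genes had no count in any library.

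The plan, fixed before the data were examined as were the groups, comparisons, gene lists, the rule for named genes and the first set of alternatives, was limma on log2 values, with edgeR in its place if a table held whole-number counts. Counts were therefore tested with the edgeR quasi-likelihood test (R 4.3.3, edgeR 4.0.16) after TMM scaling, with 1 mean per group and a spread estimated over all groups of a set. Genes with at least 10 counts in at least 3 libraries (2 in batch 1) were tested, 19444 and 15481 genes with 99.9% of the counts in each set. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with calls at an adjusted p under 0.05. The comparisons were LDL against vehicle in each genotype, each mutant genotype against WT under each treatment, Tet2KO against Dnmt3aKO, and the interaction of each mutant genotype with LDL. Effects are log2 fold changes with their standard error (SE), and levels (CPM) are counts relative to TMM-scaled library totals with the standard deviation (SD). Total counts ran from 24105237 to 43904761 in the main set and from 15171143 to 44449473 in batch 1. The common biological coefficient of variation was 0.137 and 0.199, so a gene with few counts or a change of 1.5-fold or less would often be missed. In batch 1 this also holds for a change of 2-fold.

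Named genes were chosen by a fixed rule: Dnmt3a, Tet2 and Jak2, then per comparison the 8 largest rises and 8 largest falls among genes called, with a group mean of at least 50 scaled counts and no overlap between the libraries compared, a condition dropped for interactions, and up to 4 members with the smallest adjusted p from each list that passed its test or held at least 3 called genes. Genes without a gene symbol of their own (clone and predicted names) were left out of the largest changes. Xist and the Y-linked genes were read in each library. Mpo, Ctsg, Mmp8, Mmp9 and Csf3r in Tet2KO, Gfap, Col1a1 and the genes beside Tet2 were chosen after their values were seen.

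Of 30 gene lists, written from textbook knowledge, those with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The estimated correlation replaced the preset one as an alternative, and fry asked whether the genes of a list move, on balance, one way. Counts adjusted over the list alone use the same p-values with Benjamini-Hochberg within the list. The lists covered cholesterol biosynthesis, LXR targets, lipid uptake and storage, lysosome, type I interferon response, antigen presentation and interferon gamma targets, inflammatory cytokines and NF-kB targets, chemokines, alternative activation, NRF2 and oxidative stress, ER stress and amino acid response, hypoxia and glycolysis, cell cycle, STAT5 and cytokine feedback targets, DNA methylation machinery, imprinted genes, germline genes, mitochondrial transcripts, sex-linked transcripts, and markers of macrophages (identity and resident), monocytes, neutrophils and granules, dendritic cells, T and NK cells, B cells, mast cells and basophils, megakaryocytes, erythroid cells and stromal cells.

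Recurrence in batch 1 was tested with fry on the genes called in the main set, weighted by their sign there, and by exact permutation of the libraries of batch 1 with the mean of their signed log2 values, a test chosen after the data were seen. Effects of 2 genotypes that share WT libraries were compared by Pearson's r across genes, beside the r of 100 sets of unchanged groups drawn from library residuals. Each count over groups of at least 3 libraries was set beside the counts of other splits of the same libraries, 10 splits for 3 against 3 and 100 drawn splits for an interaction. The analysis was tested on simulated data with changes of known size. In the main set edgeR recovered 29.9%, 71.6% and 90.9% of changes of 1.5, 2 and 4-fold, and in batch 1 16.4%, 52.2% and 69.7%. It made 5 false calls in each set, among 19224 and 15261 unchanged genes, and camera called the raised list and 0 of 29 others. Simulated genes varied independently and without a length trend. In the real libraries the first residual component held 25.5% and 41.6% of the within-group variance. The simulated false calls therefore do not give the rate of false calls in the real libraries.

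Alternatives were no filter, a pseudocount of 5, quantile normalization, a fit of only the groups compared, leaving out each library in turn, and the replicate number as a block, either of the titles or of the sample descriptions. Residuals of libraries with the same title number correlated across genes for each of the 3 numbers in Tet2KO against WT with LDL, and in no other comparison of the main set. In batch 1, LDL against vehicle in WT gave r = 0.199 and 0.135 for its same-number pairs. A covariate for sex was not fitted because each library had Y-linked transcripts and almost no Xist. Chosen after the data were seen were limma on scaled and on unscaled counts, DESeq2 (version 1.42.0) and its size factors, removal of each library's trend on transcript length and GC content, the first principal component of within-group residuals as a covariate, and leaving out 2 libraries with brain transcripts or, in batch 1, 2 with high stromal transcripts. Sequencing reads, single exons and DNA methylation were not analysed here.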

Results

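RNA sequencing measured transcripts in bone marrow-derived macrophages, cells grown from mouse marrow with the growth factor M-CSF. The mice carried Vav-Cre, a recombinase expressed in blood cells, and had 1 of 4 genotypes: WT, Dnmt3aKO (floxed Dnmt3a, a de novo DNA methyltransferase), Tet2KO (floxed Tet2, an enzyme that oxidises methylated DNA) and Jak2VF (an activating allele of Jak2, a kinase of cytokine receptors). These genes are mutated in clonal hematopoiesis, and the series asks how such mutations alter the macrophage transcriptome. Cells of each genotype received vehicle or low-density lipoprotein (LDL, 200 mg/dL) for 24 h. The main set held 24 libraries in 8 groups of 3, and their total counts ran from 24105237 to 43904761. Batch 1 held 10 libraries of WT and Tet2KO, 3 with vehicle and 2 with LDL for each genotype, with total counts from 15171143 to 44449473. The labels do not say whether the libraries of a group came from separate animals, so each p-value measures the spread between libraries.

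Dnmt3a (ENSMUSG00000020661, GRCm38 chromosome 12, 3806007 to 3914443) was lower in Dnmt3aKO than in WT, at -0.91 ± 0.15 on the log2 scale with vehicle (adjusted p = 2.0e-04) and -0.75 ± 0.15 with LDL (adjusted p = 0.0016). The 3 Dnmt3aKO vehicle libraries held 32.9 to 36.8 CPM (counts relative to the library total) against 55.4 to 72.1 in WT, and the 3 Dnmt3aKO LDL libraries held 27.2 to 30.8 against 39.8 to 54.6. Tet2 (ENSMUSG00000040943, chromosome 3, 133463679 to 133545139) was not lower in Tet2KO: vehicle libraries held 32.9 to 37.4 CPM against 20.2 to 32.5 in WT, and LDL libraries 19.1 to 40.2 against 14.7 to 30.1 (adjusted p = 0.568 and 0.622). In batch 1 the ranges were 16.7 to 24.4 and 24.0 to 28.1 CPM with vehicle, and 20.8 to 21.4 and 16.9 to 35.9 with LDL. A count over the whole gene includes exons that a floxed allele keeps, so these values do not test the Tet2KO label. Jak2 (ENSMUSG00000024789, chromosome 19, 29251828 to 29313080) held 54.7 to 68.5 CPM in Jak2VF against 80.0 to 92.8 in WT with vehicle (-0.50 ± 0.13, adjusted p = 0.0209), and 64.7 to 75.1 against 70.0 to 97.3 with LDL (adjusted p = 0.273). The vehicle difference in Jak2 was lost without WT vehicle library 2 (log2 fold change -0.49, adjusted p = 0.0647), WT vehicle library 3 (log2 fold change -0.44, adjusted p = 0.0979), Jak2VF vehicle library 1 (log2 fold change -0.41, adjusted p = 0.128) or Jak2VF vehicle library 2 (log2 fold change -0.46, adjusted p = 0.0991). Reads that would show the altered Jak2 base are not part of a count table, so the Jak2VF label was not tested either.

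In WT macrophages LDL lowered transcripts of cholesterol synthesis and raised Abcg1 and Mylip. Idi1, which makes a precursor of sterols, fell from 76.3 ± 7.98 to 14.2 ± 1.09 CPM (SD, n = 3 each; log2 fold change -2.40 ± 0.09, SE). Cyp51, a sterol demethylase, fell by 1.79 ± 0.08 on the log2 scale, and Insig1, which retains the sterol sensor complex in the endoplasmic reticulum, fell by 1.75 ± 0.07. In the cholesterol biosynthesis list 22 of 25 fell and 3 did not pass (23 fell adjusted over the list alone, camera adjusted p = 7.3e-32, or 1.6e-04 with an estimated correlation). Abcg1 (chromosome 17, 31057675 to 31117988), a transporter that passes cholesterol to lipoproteins, rose from 24.5 ± 1.34 to 178 ± 13.1 CPM (2.88 ± 0.11, adjusted p = 1.5e-13). Mylip, which marks the LDL receptor for degradation, rose by 1.11 ± 0.08. Among LXR targets, genes of a nuclear receptor for oxidised sterols, 6 of 15 rose, 3 fell and 6 did not pass (6 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.0124, or 0.0387 with an estimated correlation). In the lipid uptake and storage list 9 of 20 rose, 2 fell and 9 did not pass (9 rose and 2 fell adjusted over the list alone, camera adjusted p = 8.4e-05, or 0.00206 with an estimated correlation). Plin2, a coat protein of lipid droplets, rose by 1.44 ± 0.13 and Hilpda, which blocks lipid droplet breakdown, by 2.33 ± 0.18.

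LDL also raised Cxcl3, Cxcl2 and targets of NRF2, a regulator of antioxidant genes, in WT cells. Cxcl3 rose by 3.96 ± 0.20 to 230.4 ± 35.8 CPM and Cxcl2 from 8.84 ± 3.10 to 127 ± 12.4 CPM (3.87 ± 0.24, n = 3 each). In the chemokine list 12 of 19 rose, 2 fell and 5 did not pass (12 rose and 4 fell adjusted over the list alone, camera adjusted p = 1.1e-06, or 0.231 with an estimated correlation). In the list of inflammatory cytokines and NF-kB targets 10 of 19 rose, 1 fell and 8 did not pass (12 rose and 2 fell adjusted over the list alone, camera adjusted p = 4.7e-08, or 0.00206 with an estimated correlation). Il1a rose by 3.37 ± 0.29 and Nos2, the inducible nitric oxide synthase, by 2.42 ± 0.17. In the NRF2 list 13 of 15 rose and 2 did not pass (15 rose adjusted over the list alone, camera adjusted p = 2.6e-18, or 0.00206 with an estimated correlation). Nqo1, a quinone reductase, rose by 2.74 ± 0.12 and Srxn1, a sulfiredoxin, by 1.18 ± 0.10. For hypoxia and glycolysis 10 of 18 rose and 8 did not pass (14 rose adjusted over the list alone, camera adjusted p = 1.1e-07, or 0.0409 with an estimated correlation), and Vegfa, an angiogenic factor, stood at 0.85 ± 0.10.

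Cell cycle transcripts fell with LDL in WT: 24 of 25 fell and 1 did not pass (25 fell adjusted over the list alone, camera adjusted p = 1.1e-24, or 0.00206 with an estimated correlation). Ccna2, a cyclin of S phase, fell by 1.28 ± 0.11 and Aurkb, a mitotic kinase, by 0.89 ± 0.09. In the list of resident macrophage markers 9 of 17 fell, 2 rose and 6 did not pass (10 fell and 2 rose adjusted over the list alone, camera adjusted p = 4.0e-06, or 0.0137 with an estimated correlation). Gas6, a ligand of the receptor Mertk, fell by 1.35 ± 0.11 and Maf, a transcription factor, by 0.80 ± 0.08. In the neutrophil and granule list, markers of another cell type, 5 of 15 fell, 2 rose and 8 did not pass (5 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.15, or 0.584 with an estimated correlation). Across 19444 genes tested with edgeR, 2770 differed between LDL and vehicle in WT, 1296 higher and 1474 lower. Values of Idi1, Cxcl2, Cxcl3 and Il1a did not overlap between the 3 LDL and the 3 vehicle libraries. When only the WT libraries were fitted 1261 genes differed, with the description number as a block 597, and 1124 did so with limma on unscaled counts.

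**Figure D1:**
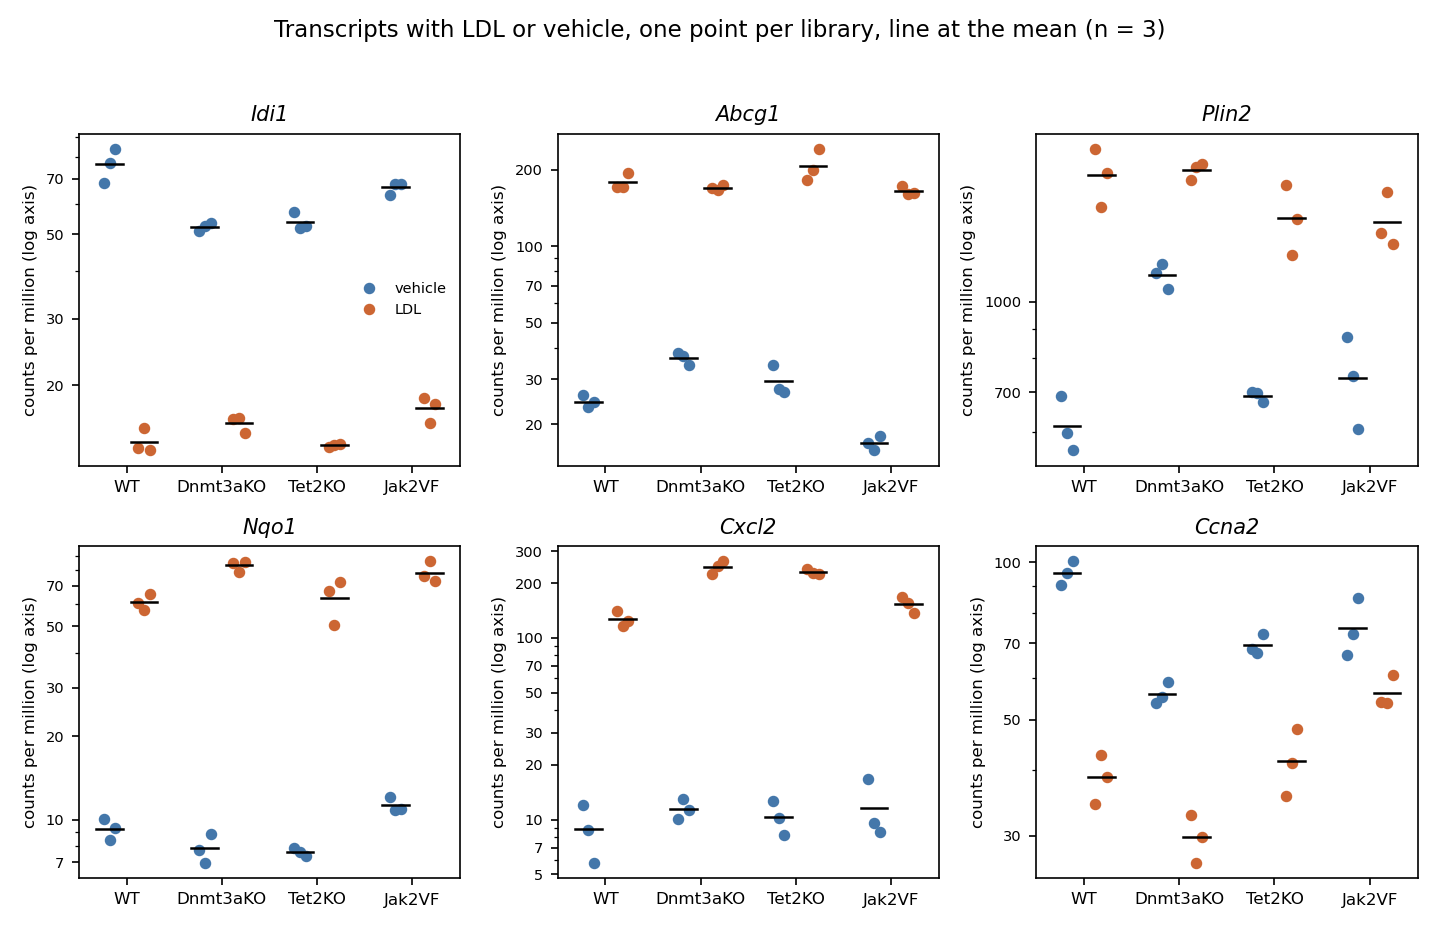
CPM (log axis) of Idi1, Abcg1, Plin2, Nqo1, Cxcl2 and Ccna2 in each library of the main set, by genotype and treatment, with a horizontal line at the mean of 3 libraries. Idi1 lies lower and Abcg1 higher with LDL than with vehicle in each genotype, with log2 fold changes in WT of -2.40 and 2.88.

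The same question was asked within each mutant genotype. Idi1 fell by 1.68 ± 0.09 on the log2 scale in Dnmt3aKO, 1.95 ± 0.09 in Tet2KO and 1.93 ± 0.09 in Jak2VF, and Abcg1 rose by 2.26 ± 0.10, 2.81 ± 0.11 and 3.30 ± 0.11. Cxcl2 rose by 4.46 ± 0.24, 4.47 ± 0.24 and 3.71 ± 0.24, and Nqo1 by 3.43 ± 0.12, 3.05 ± 0.12 and 2.79 ± 0.12 (SE, n = 3 libraries per group). Of 25 cholesterol biosynthesis genes, 21 fell in Dnmt3aKO (camera adjusted p = 1.9e-23, or 4.6e-04 with an estimated correlation), 19 in Tet2KO (camera adjusted p = 1.9e-23, or 4.6e-04 with an estimated correlation) and 23 in Jak2VF (camera adjusted p = 3.2e-30, or 2.1e-04 with an estimated correlation). Of 15 NRF2 genes, 13 rose in each of the 3 (camera adjusted p = 1.3e-22, or 0.00114 with an estimated correlation in Dnmt3aKO, camera adjusted p = 4.0e-16, or 0.00443 with an estimated correlation in Tet2KO, camera adjusted p = 2.3e-14, or 0.00739 with an estimated correlation in Jak2VF). The inflammatory list held 13, 13 and 12 genes that rose, of 19 (camera adjusted p = 2.3e-16, or 8.4e-05 with an estimated correlation, camera adjusted p = 7.0e-13, or 3.7e-04 with an estimated correlation and camera adjusted p = 9.0e-07, or 0.00635 with an estimated correlation). Of 17 resident macrophage markers 10 fell in Dnmt3aKO, 9 in Tet2KO and 10 in Jak2VF (camera adjusted p = 1.4e-10, or 0.00141 with an estimated correlation, camera adjusted p = 4.9e-07, or 0.00859 with an estimated correlation and camera adjusted p = 9.0e-07, or 0.00965 with an estimated correlation).

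Cell cycle genes fell as well. In Dnmt3aKO 20 of 25 fell and 5 did not pass (22 fell adjusted over the list alone, camera adjusted p = 5.6e-16, or 0.0103 with an estimated correlation). In Tet2KO 14 of 25 fell and 11 did not pass (19 fell adjusted over the list alone, camera adjusted p = 1.0e-09, or 0.0516 with an estimated correlation). In Jak2VF 11 of 25 fell and 14 did not pass (13 fell adjusted over the list alone, camera adjusted p = 9.0e-07, or 0.124 with an estimated correlation). Ccnb2, a mitotic cyclin, fell by 1.10 ± 0.13, 0.79 ± 0.13 and 0.96 ± 0.13. Neutrophil and granule transcripts also moved with LDL: in Dnmt3aKO 10 of 15 fell, 2 rose and 3 did not pass (10 fell and 2 rose adjusted over the list alone, camera adjusted p = 7.0e-04, or 0.191 with an estimated correlation). In Jak2VF 11 of 15 fell, 2 rose and 2 did not pass (11 fell and 2 rose adjusted over the list alone, camera adjusted p = 4.3e-06, or 0.0771 with an estimated correlation). Ltf, the granule protein lactoferrin, fell by 1.13 ± 0.12 in Dnmt3aKO, while Mmp8, a neutrophil collagenase, rose by 2.02 ± 0.12 there and by 1.61 ± 0.12 in Jak2VF. In all, 2988 genes differed with LDL in Dnmt3aKO (1246 higher, 1742 lower), 3267 in Tet2KO (1671 higher, 1596 lower) and 3532 in Jak2VF (1642 higher, 1890 lower). Their order is not firm: a fit of only the groups compared gave 5542, 1472 and 2396, and the description number as a block 867, 712 and 543. The Jak2VF count was 2347 without vehicle library 1, 2244 without vehicle library 2, 2028 without LDL library 1 and 2289 without LDL library 3.

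Interaction terms tested whether the LDL response differed from that of WT. In Dnmt3aKO 84 genes differed, 37 with a higher and 47 with a lower LDL effect than in WT. Serpinb2, an inhibitor of plasminogen activators, had an LDL effect larger by 1.59 ± 0.23 (adjusted p = 0.00117), Met, the hepatocyte growth factor receptor, by 1.51 ± 0.23, and Nlrp3, an inflammasome sensor, by 1.07 ± 0.15. Idi1 fell less than in WT, with a difference of 0.72 ± 0.12 (adjusted p = 0.00489). The effect on Angptl4, an inhibitor of lipoprotein lipase, was lower by -1.76 ± 0.28, that on Ppbp, a platelet chemokine, by -1.32 ± 0.19, and that on Bmp4, a bone morphogenetic protein, by -1.88 ± 0.26. In the cholesterol biosynthesis list 2 of 25 had a higher effect and 23 did not pass (11 had a higher effect adjusted over the list alone, camera adjusted p = 9.3e-07, or 0.183 with an estimated correlation). In the inflammatory list 2 of 19 had a higher effect and 17 did not pass (5 had a higher effect and 1 had a lower effect adjusted over the list alone, camera adjusted p = 0.0029, or 0.183 with an estimated correlation). The count of genes was 132, 46 and 41 without WT vehicle libraries 1, 2 and 3, 645 and 48 without WT LDL libraries 2 and 3, 45 and 45 without Dnmt3aKO vehicle libraries 2 and 3, and 48 and 42 without Dnmt3aKO LDL libraries 1 and 3. With only these 12 libraries fitted it was 50, and with limma on unscaled counts 14.

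In Tet2KO 20 genes differed from WT in their LDL response, 8 with a higher and 12 with a lower effect. Gprc5c, an orphan receptor, had an LDL effect lower by -1.25 ± 0.17 (adjusted p = 0.00416). Ciita, the regulator of class II genes, had one lower by -2.04 ± 0.36 (adjusted p = 0.0276), while H2-Aa (-1.77 ± 0.36) and H2-Eb1 (-1.40 ± 0.34), which encode chains of class II molecules, did not pass (adjusted p = 0.0554 and 0.141), although both did with DESeq2, and H2-Aa without WT LDL library 2. The title number, by which residuals correlate in Tet2KO and WT with LDL, changes these calls: as a block it gave 40 genes, H2-Aa among them, and as a block within genotype 8, with H2-Aa and H2-Eb1 but not Ciita or Cdcp1. With 1 library left out, Ciita stayed called only without WT vehicle library 3, WT LDL library 1 or 2, Tet2KO vehicle library 3 or Tet2KO LDL library 2 (adjusted p up to 0.111 otherwise). In the list of antigen presentation and interferon gamma targets 1 of 20 had a lower effect and 19 did not pass (6 had a lower effect adjusted over the list alone, camera adjusted p = 2.7e-10, or 0.202 with an estimated correlation). In the cell cycle list 0 of 25 genes passed (16 had a higher effect adjusted over the list alone, camera adjusted p = 3.4e-16, or 0.0503 with an estimated correlation). The count was 9, 2 and 10 without WT vehicle libraries 1, 2 and 3, 12 without WT LDL library 3, 12 and 2 without Tet2KO vehicle libraries 1 and 2, and 8, 41 and 5 without Tet2KO LDL libraries 1, 2 and 3. With edgeR 0 genes passed when only these 12 libraries were fitted, so Gprc5c, Ciita and Cdcp1 were no longer called, and 0 without both LDL libraries that held transcripts of brain (WT 3 and Tet2KO 3), against 169 with DESeq2 on all libraries, and 1428 had an unadjusted p under 0.05 with every library fitted.

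In Jak2VF 480 genes differed from WT in their LDL response, 293 with a higher and 187 with a lower effect. LDL effects on antigen presentation were lower for H2-Eb1 by -2.38 ± 0.35 (adjusted p = 0.00293) and for H2-Aa by -2.05 ± 0.37: within Jak2VF, H2-Eb1 fell from 10.8 ± 2.86 to 2.53 ± 0.377 CPM. In the list of antigen presentation and interferon gamma targets 4 of 20 had a lower effect and 16 did not pass (14 had a lower effect adjusted over the list alone, camera adjusted p = 7.4e-08, or 0.53 with an estimated correlation). Among cell cycle genes, Top2a, a topoisomerase, fell less than in WT, by 1.21 ± 0.22, and Ccna2 by 0.87 ± 0.16. In that list 10 of 25 had a higher effect and 15 did not pass (16 had a higher effect adjusted over the list alone, camera adjusted p = 2.7e-09, or 0.254 with an estimated correlation). The effect on Angptl4 was lower by -1.52 ± 0.28. The count of genes was 1568, 110 and 107 without WT vehicle libraries 1, 2 and 3, 100, 3600 and 190 without WT LDL libraries 1, 2 and 3, 111, 120 and 3003 without Jak2VF vehicle libraries 1, 2 and 3, and 115, 872 and 91 without Jak2VF LDL libraries 1, 2 and 3. With only these 12 libraries fitted it was 22, and Top2a, Ccna2, H2-Aa, Angptl4 and Cdcp1 were no longer called. Cdcp1, a membrane glycoprotein, had a larger LDL effect in Dnmt3aKO (1.83 ± 0.30), Tet2KO (1.60 ± 0.28) and Jak2VF (1.65 ± 0.28) than in WT. In Tet2KO, with 1 library left out, it stayed called only without WT vehicle library 3, WT LDL library 1 or 3 or Tet2KO LDL library 2 (adjusted p up to 0.102 otherwise). With the description number as a block within genotype, which leaves 4 residual degrees of freedom, none of the genes named in the 3 interactions was called.

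Dnmt3aKO macrophages were compared with WT under each treatment to ask what loss of Dnmt3a changed. Gdf3, a ligand of the TGF-beta family (chromosome 6, 122605403 to 122610087), was higher at 23.4 ± 1.90 against 1.16 ± 0.213 CPM with vehicle (4.33 ± 0.16, adjusted p = 4.6e-13) and 4.26 ± 0.17 with LDL. Apoc1, an apolipoprotein, rose by 4.43 ± 0.38 and 3.01 ± 0.36, while C2, a complement protease, rose by 2.80 ± 0.21 and Tnfsf4, a costimulatory ligand, by 3.66 ± 0.21 with LDL. Eps8l1, an actin regulator, fell by 3.07 ± 0.15 and 3.70 ± 0.16, and Fgf10, a fibroblast growth factor, by 2.21 ± 0.16 and 2.46 ± 0.15. Il33, an alarmin cytokine, fell by 2.12 ± 0.14 with vehicle. Among imprinted genes with vehicle 7 of 19 fell and 12 did not pass (8 fell adjusted over the list alone, camera adjusted p = 1.6e-05, or 0.028 with an estimated correlation). Igf2, a growth factor, fell by 1.52 ± 0.16, and the non-coding RNAs H19 and Rian by 1.21 ± 0.17 and 1.33 ± 0.16. Each library of the main set also held Col1a1, a collagen of stromal cells, at levels given below. Which cells held the transcripts named here was not tested.

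Granule protein and monocyte transcripts were higher in Dnmt3aKO. S100a9, a calcium-binding protein of neutrophils and monocytes, was among 13 of 15 granule markers that rose with vehicle (camera adjusted p = 9.4e-24, or 5.3e-04 with an estimated correlation) and 12 with LDL (camera adjusted p = 2.1e-12, or 0.009 with an estimated correlation). Their summed level was 873 ± 27.7 CPM in Dnmt3aKO and 309.8 ± 37.1 in WT with vehicle (SD, n = 3). Ltf rose by 1.54 ± 0.12 and 1.03 ± 0.12, and Retnlg, a resistin-like protein, by 2.51 ± 0.22 and 2.23 ± 0.23. For monocyte markers 7 of 9 rose and 2 did not pass (8 rose adjusted over the list alone, camera adjusted p = 4.5e-12, or 0.0026 with an estimated correlation) with vehicle. Ly6c2, a monocyte surface protein, rose by 2.18 ± 0.19. Of B cell markers 6 of 8 rose and 2 did not pass (7 rose adjusted over the list alone, camera adjusted p = 2.7e-09, or 0.00468 with an estimated correlation). Of T and NK cell markers with LDL 6 of 12 fell and 6 did not pass (7 fell adjusted over the list alone, camera adjusted p = 1.2e-05, or 0.0411 with an estimated correlation). Ncr1, an NK cell receptor, held 0.347 ± 0.205 against 1.41 ± 0.142 CPM.

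Inflammatory and antioxidant transcripts were higher and cell cycle transcripts lower in Dnmt3aKO. In the inflammatory list 11 of 19 rose, 2 fell and 6 did not pass (12 rose and 4 fell adjusted over the list alone, camera adjusted p = 7.9e-06, or 0.00634 with an estimated correlation) with vehicle. Nos2 rose by 2.04 ± 0.17 and Lcn2, an iron-binding protein, by 1.98 ± 0.22. With LDL 14 of 19 rose and 5 did not pass (14 rose adjusted over the list alone, camera adjusted p = 1.8e-11, or 7.3e-04 with an estimated correlation). Il1a rose by 2.37 ± 0.20 and Csf3, a granulocyte growth factor, by 2.71 ± 0.25. Of NRF2 targets 7 of 15 rose with vehicle (camera adjusted p = 2.6e-10, or 0.0155 with an estimated correlation) and 12 with LDL (camera adjusted p = 2.1e-12, or 0.0128 with an estimated correlation), with Gclm, which serves glutathione synthesis, at 0.95 ± 0.09 and 1.19 ± 0.09. Cd36, a scavenger receptor, rose by 1.08 ± 0.10 and 1.55 ± 0.10, and in the lipid uptake and storage list 7 of 20 rose and 13 did not pass (8 rose adjusted over the list alone, camera adjusted p = 7.5e-08, or 4.0e-04 with an estimated correlation) with vehicle. Of cell cycle genes 23 of 25 fell and 2 did not pass (25 fell adjusted over the list alone, camera adjusted p = 2.2e-27, or 0.00158 with an estimated correlation) with vehicle. With LDL 19 of 25 fell and 6 did not pass (19 fell adjusted over the list alone, camera adjusted p = 3.7e-11, or 0.033 with an estimated correlation). Mcm6, a replication helicase subunit, fell by 0.76 ± 0.08 and 0.60 ± 0.08. In the cholesterol biosynthesis list with vehicle 10 of 25 fell and 15 did not pass (12 fell adjusted over the list alone, camera adjusted p = 9.5e-09, or 0.0155 with an estimated correlation). With vehicle 2157 genes differed (1085 higher, 1072 lower), and with LDL 3397 (1557 higher, 1840 lower). The LDL count was 1976, 5795 and 1982 without WT LDL libraries 1, 2 and 3, and 2152 and 1842 without Dnmt3aKO LDL libraries 2 and 3, and it was 1284 with only these 6 libraries fitted. Log2 fold changes correlated with transcript length across genes with LDL (Spearman's rho = 0.487), but hardly with vehicle (0.0606).

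Tet2KO cultures had higher Gdf3 and lower Ngp, Ltf and S100a9 than WT. Gdf3 was at 12.7 ± 0.604 against 1.16 ± 0.213 CPM with vehicle (3.47 ± 0.16, adjusted p = 8.2e-12) and rose by 3.65 ± 0.17 with LDL, and Xlr3b, an X-linked lymphocyte-regulated gene, by 2.46 ± 0.14 and 2.08 ± 0.14. Ngp, a neutrophil granule protein, fell by 2.94 ± 0.18 and 2.77 ± 0.19, Ltf by 2.71 ± 0.14 and 2.61 ± 0.14, and S100a9 (chromosome 3, 90692632 to 90695721) from 88.5 ± 16.8 to 15.5 ± 1.84 CPM with vehicle (-2.49 ± 0.19). In the granule list with vehicle 6 of 15 fell, 5 rose and 4 did not pass (7 fell and 6 rose adjusted over the list alone, camera adjusted p = 0.00188, or 0.229 with an estimated correlation). The members that rose were Mpo and Ctsg, proteins of primary granules, Mmp8, Mmp9, a gelatinase, and Csf3r, the receptor of a granulocyte growth factor. Calls of 4 of these rested on single libraries (log2 fold change and adjusted p in brackets): Mpo was lost without WT vehicle library 1 (0.74, p 0.091), WT vehicle library 2 (0.74, p 0.103), Tet2KO vehicle library 1 (0.80, p 0.0681) or Tet2KO vehicle library 2 (0.75, p 0.089). Ctsg was lost without WT vehicle library 1 (0.89, p 0.106), WT vehicle library 3 (0.86, p 0.112), Tet2KO vehicle library 1 (0.95, p 0.0727) or Tet2KO vehicle library 2 (0.81, p 0.137), and it and Mmp8 with only the WT and Tet2KO vehicle libraries fitted. Mmp8 was lost without WT vehicle library 3 (0.50, p 0.0506), Tet2KO vehicle library 1 (0.35, p 0.114) or Tet2KO vehicle library 2 (0.49, p 0.0573), and Mmp9 without WT vehicle library 3 (0.43, p 0.113) or Tet2KO vehicle library 3 (0.40, p 0.128). Chil3, a chitinase-like protein of monocytes and neutrophils, fell by 2.33 ± 0.14 and 2.23 ± 0.14. Among T and NK cell markers 9 of 12 rose and 3 did not pass (12 rose adjusted over the list alone, camera adjusted p = 1.9e-12, or 0.00989 with an estimated correlation) with vehicle. Lck, a T cell kinase, was at 5.74 ± 0.0616 against 2.76 ± 0.689 CPM, and Ncr1 rose by 1.45 ± 0.25. Of B cell markers with vehicle 5 of 8 rose and 3 did not pass (5 rose adjusted over the list alone, camera adjusted p = 5.4e-06, or 0.027 with an estimated correlation). Cx3cr1, the fractalkine receptor, rose by 0.79 ± 0.08 and 1.04 ± 0.08.

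Lists of cell division and sterol synthesis were lower in Tet2KO with vehicle. Of cell cycle genes 15 of 25 fell and 10 did not pass (22 fell adjusted over the list alone, camera adjusted p = 2.7e-17, or 0.0193 with an estimated correlation). Mcm6 fell by 0.56 ± 0.08 and Pcna, a replication clamp, by 0.57 ± 0.10. Of cholesterol biosynthesis genes 7 of 25 fell and 18 did not pass (11 fell adjusted over the list alone, camera adjusted p = 7.6e-09, or 0.027 with an estimated correlation). Idi1 fell by 0.48 ± 0.08. Cd36 fell by 0.76 ± 0.10. Of resident macrophage markers with LDL 5 of 17 fell and 12 did not pass (8 fell adjusted over the list alone, camera adjusted p = 1.0e-06, or 0.0263 with an estimated correlation). C1qa, a complement component, fell by 1.06 ± 0.20 and Gas6 by 0.83 ± 0.11. Alpk1, a kinase that senses bacterial sugars and lies on the same chromosome as Tet2 (chromosome 3, 127670310 to 127780527), rose by 1.81 ± 0.19 with LDL, and the pseudogenes Rpl34-ps1 and Rpl34-ps2 rose by 3.67 ± 0.58 and 3.68 ± 0.33 with vehicle while their parent gene Rpl34, on the Tet2 chromosome, held 134 ± 9.64 against 259 ± 56.7 CPM. With vehicle 1064 genes differed (536 higher, 528 lower), a count that was 649 without WT vehicle library 2 and 644 without Tet2KO vehicle library 2. With LDL 537 differed (249 higher, 288 lower), 814 without WT LDL library 2, and 38 with only these 6 libraries fitted, where C1qa and Gas6 were no longer called. Spearman's rho of the log2 fold changes with transcript length was 0.438 with vehicle and 0.467 with LDL. WT and Tet2KO LDL libraries 3 held 2.67 and 4.25 CPM of Gfap, a filament protein of astrocytes, and without them 289 genes differed. In that comparison residuals of samples with the same title number correlated (r = 0.501, 0.486 and 0.311 across genes, which are not independent replicates), and with that number as a block 608 genes differed.

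Jak2VF cultures had higher megakaryocyte, mast cell and granule transcripts and lower resident macrophage transcripts than WT. The labels name no sort, so a changed mix of cells and a change within macrophages cannot be told apart here. Itga2b, the platelet integrin chain CD41 gene, rose from 5.80 ± 1.51 to 22.2 ± 2.87 CPM with vehicle (1.94 ± 0.20, adjusted p = 3.2e-06), and of megakaryocyte markers 8 of 10 rose and 2 did not pass (9 rose adjusted over the list alone, camera adjusted p = 5.1e-12, or 0.00486 with an estimated correlation). Capn11, a calpain protease, rose by 5.86 ± 0.45 with vehicle and 5.85 ± 0.48 with LDL. Of mast cell and basophil markers 4 of 7 rose and 3 did not pass (5 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.00104, or 0.0192 with an estimated correlation). Hdc, which makes histamine, rose by 1.77 ± 0.19, and Prss34, a basophil protease, was at 2.36 ± 0.726 against 0.00946 ± 0.0164 CPM. In the granule list 10 of 15 rose and 5 did not pass (14 rose adjusted over the list alone, camera adjusted p = 3.5e-17, or 0.00486 with an estimated correlation) with vehicle. Ltf rose by 1.42 ± 0.12 and S100a9 by 1.65 ± 0.18. Of monocyte markers 6 of 9 rose and 3 did not pass (7 rose adjusted over the list alone, camera adjusted p = 1.5e-06, or 0.0318 with an estimated correlation). Ly6c2 rose by 1.31 ± 0.19. Slc15a2, a peptide transporter, fell by 3.16 ± 0.23 and 2.39 ± 0.23.

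Resident macrophage markers were lower in Jak2VF: with vehicle 9 of 17 fell and 8 did not pass (11 fell adjusted over the list alone, camera adjusted p = 1.1e-08, or 0.00486 with an estimated correlation). With LDL 13 of 17 fell and 4 did not pass (13 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.6e-10, or 0.0058 with an estimated correlation). Maf fell by 0.60 ± 0.08 and 0.61 ± 0.08 and Gas6 by 0.73 ± 0.10 and 0.72 ± 0.11. Adgre1, the macrophage antigen F4/80 gene, fell from 1204 ± 38.5 to 751 ± 40.4 CPM with vehicle, and of macrophage identity genes with LDL 11 of 14 fell and 3 did not pass (13 fell adjusted over the list alone, camera adjusted p = 1.7e-10, or 0.0266 with an estimated correlation). Of interferon response genes with vehicle 15 of 28 fell and 13 did not pass (21 fell adjusted over the list alone, camera adjusted p = 1.8e-12, or 0.234 with an estimated correlation). Rsad2, an antiviral enzyme, fell by 2.36 ± 0.39 and Ifit2, an antiviral RNA-binding protein, by 1.61 ± 0.25. Of antigen presentation genes with LDL 14 of 20 fell and 6 did not pass (20 fell adjusted over the list alone, camera adjusted p = 1.0e-11, or 0.144 with an estimated correlation). H2-Eb1 fell by 1.35 ± 0.26 and Irf8, a transcription factor of macrophages and dendritic cells, by 0.78 ± 0.09. With vehicle 1857 genes differed (835 higher, 1022 lower), and the count was 1061 and 1005 without WT vehicle libraries 2 and 3, and 1145 and 1102 without Jak2VF vehicle libraries 1 and 2. With LDL 1938 differed (819 higher, 1119 lower), 695, 4492 and 1119 without WT LDL libraries 1, 2 and 3, and 747 and 631 without Jak2VF LDL libraries 1 and 3. Fitting only the groups compared gave 724 and 264, and Jak2 was not called with vehicle there. Spearman's rho of the Jak2VF log2 fold changes with transcript length was -0.405 with vehicle and 0.544 with LDL.

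**Figure D2:**
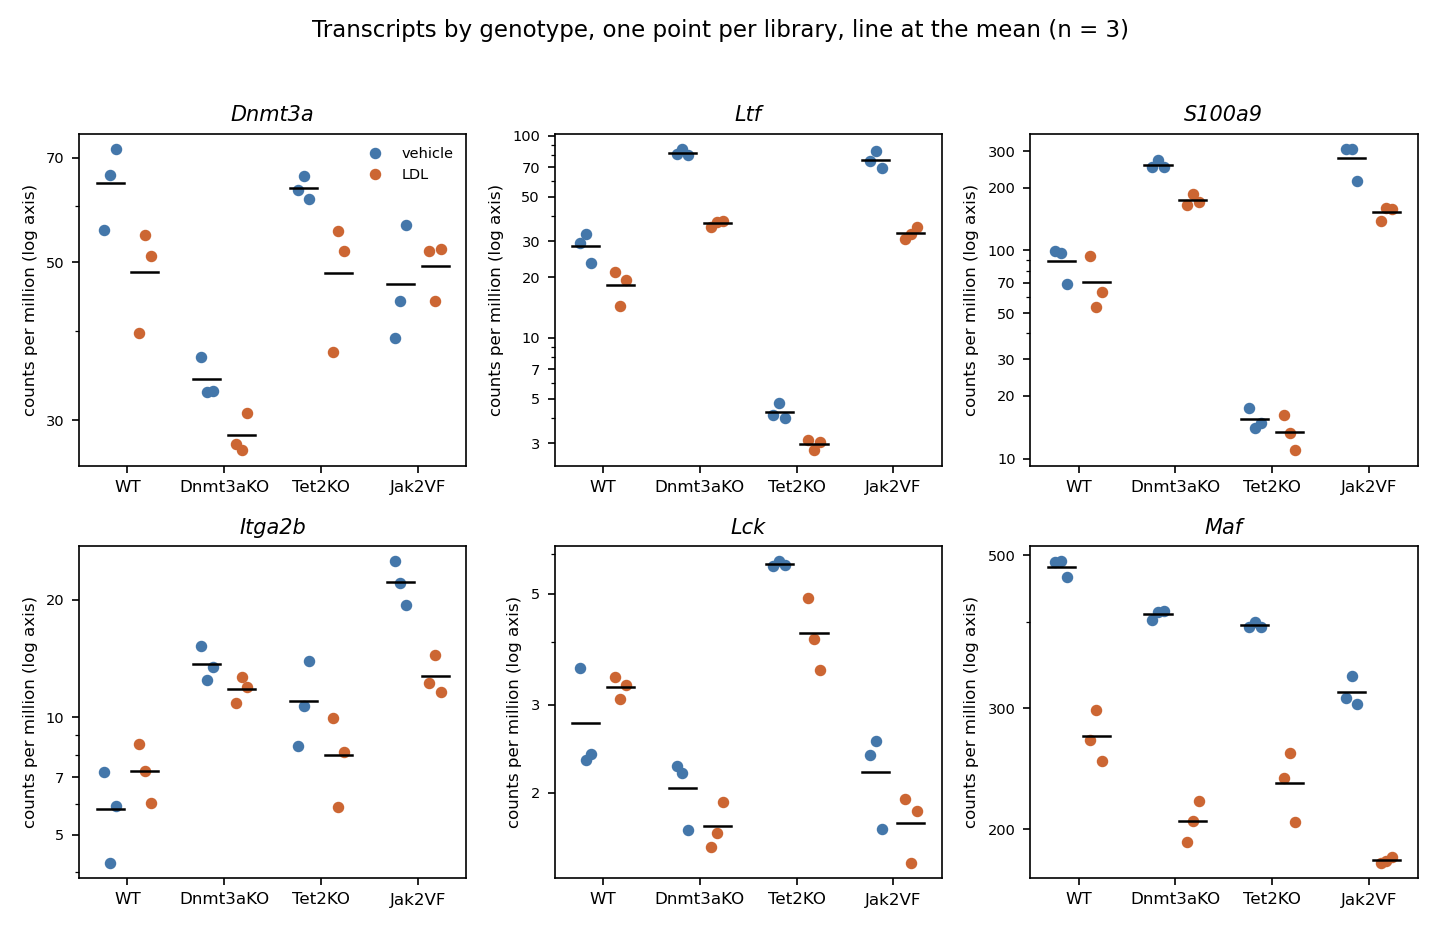
CPM (log axis) of Dnmt3a, Ltf, S100a9, Itga2b, Lck and Maf in each library of the main set, by genotype and treatment, with a horizontal line at the mean of 3 libraries. Ltf lies highest in Dnmt3aKO and Jak2VF and lowest in Tet2KO with vehicle, at means of 82.7, 76.1 and 4.29 CPM against 28.6 in WT.

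The knockouts of Dnmt3a and Tet2 were also compared with each other, without a shared control. Granule transcripts were lower in Tet2KO than in Dnmt3aKO, with S100a9 at 15.5 ± 1.84 against 258 ± 11.2 CPM with vehicle (-4.04 ± 0.20), Ltf at -4.25 ± 0.14 and Retnlg at -5.45 ± 0.29. In the granule list 13 of 15 fell and 2 did not pass (14 fell adjusted over the list alone, camera adjusted p = 1.4e-29, or 1.4e-04 with an estimated correlation). T and NK cell markers were higher in Tet2KO, 12 of 12 rose (12 rose adjusted over the list alone, camera adjusted p = 3.9e-18, or 4.7e-04 with an estimated correlation). Lck rose by 1.51 ± 0.18 and Klrb1c, an NK cell lectin, by 2.50 ± 0.29. In the lipid uptake and storage list 11 of 20 fell and 9 did not pass (11 fell adjusted over the list alone, camera adjusted p = 3.5e-11, or 3.1e-05 with an estimated correlation). Cd36 was at 168 ± 13.7 against 611 ± 34.2 CPM. Of NRF2 targets 10 of 15 fell and 5 did not pass (12 fell adjusted over the list alone, camera adjusted p = 7.2e-11, or 0.015 with an estimated correlation). With vehicle 1707 genes differed between the knockouts (794 higher and 913 lower in Tet2KO), and with LDL 2203 (1223 higher, 980 lower). With only the groups compared fitted, the counts were 3443 and 975.

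Effects of both knockouts against the same WT libraries correlated across genes, with r = 0.374 with vehicle and 0.422 with LDL, where genes are not independent replicates. Shared controls alone gave a median r of 0.517 and 0.549 over 100 simulated sets of unchanged groups. Covariance, which effects proper to 1 genotype do not dilute as they do r, was 0.0785 beside a simulated median of 0.0429 with vehicle (12 of 100 sets as large) and 0.0974 beside 0.0495 with LDL (5 of 100, but 1 without WT LDL library 2 and 28 without Tet2KO LDL library 2). Whether the knockouts share effects beyond the shared WT libraries thus stays open. Calls overlapped: 224 genes were higher in both knockouts with vehicle against 29.9 expected of independent calls, and 263 were lower against 29.1, an expectation that the shared controls raise by an amount not estimated. With LDL 117 were higher against 19.9 and 108 lower against 27.3. In opposite directions it was 105 against 59.0 with vehicle and 90 against 46.6 with LDL. With Tet2KO effects from batch 1, which share no libraries with the Dnmt3aKO effects, r was -0.157 with vehicle and -0.128 with LDL, within the ranges of 100 simulations without an effect (-0.457 to 0.463 and -0.438 to 0.437), and 95 and 92 of the 100 had a covariance as large. For Jak2VF with those effects it was 0.111 and 0.073, also within them (-0.504 to 0.471 and -0.468 to 0.482, with a covariance that 4 and 14 of 100 reached). Jak2VF and Tet2KO effects gave r = 0.241 and 0.484, beside simulated medians of 0.535 and 0.542, and 43 and 7 of 100 sets had a covariance as large. With 1 library left out, r ran from 0.126 to 0.333 with vehicle (21 to 83 of 100) and from 0.321 to 0.652 with LDL (0, without WT LDL library 2, to 19 of 100).

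**Figure D3:**
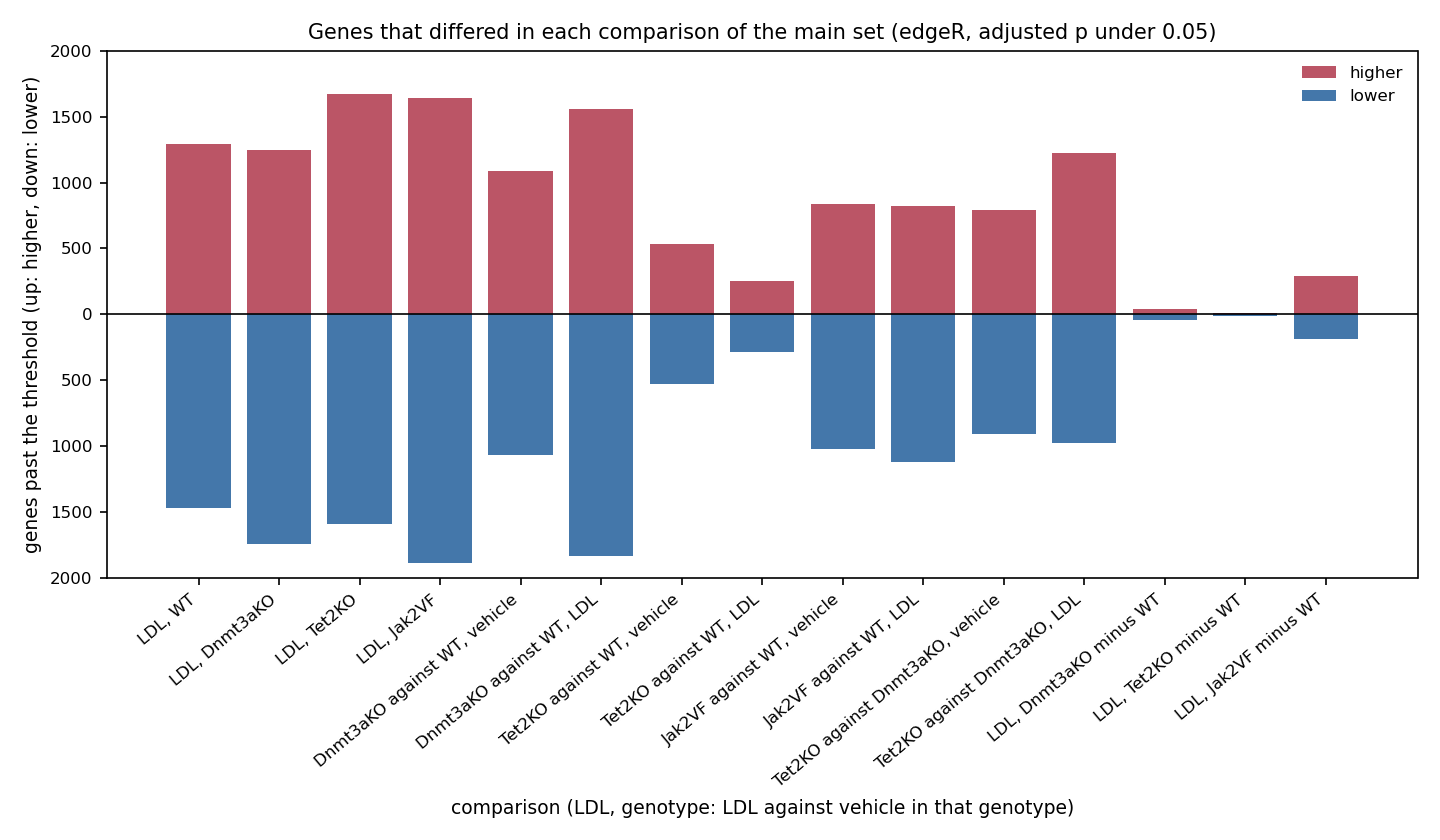
Genes higher (bars upward) and lower (bars downward) in each of the 15 comparisons of the main set, by edgeR at an adjusted p under 0.05 over 19444 genes tested. Counts for LDL against vehicle run from 2770 genes in WT to 3532 in Jak2VF.

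Batch 1 asked whether the Tet2KO and LDL effects recurred in other libraries. With vehicle 23 genes were called higher in Tet2KO in both sets, against 3.21 expected of independent calls, and 51 lower against 5.66. Itgax, the integrin chain CD11c gene, was at 5.82 ± 2.19 CPM in Tet2KO of batch 1 against 93.1 ± 29.4 in WT with vehicle (adjusted p = 0.00169). It was not among the genes called lower in both sets. Cd55, a complement inhibitor, rose by 2.58 ± 0.19 and 3.26 ± 0.24. Rpl34-ps1 and Rpl34-ps2 rose by 3.53 ± 0.30 and 5.57 ± 0.41 with vehicle. Of granule markers 2 of 14 fell and 12 did not pass (12 fell adjusted over the list alone, camera adjusted p = 2.1e-09, or 0.19 with an estimated correlation). Col1a1 held 679 ± 743 against 195 ± 70.8 CPM. Of the genes called for Tet2KO in the main set, 587 of 919 (63.9%) had the same sign in batch 1 with vehicle (fry p = 0.00674, exact permutation p = 0.1 over 20 groupings). With LDL it was 372 of 466 (79.8%) (fry p = 1.8e-05, exact permutation p = 0.333 over 6). These exact values are the smallest that so few libraries can give, and fry, which draws on the residual spread, tests whether the genes move, on balance, with their main set sign. Of 15481 genes tested in batch 1, 292 differed between Tet2KO and WT with vehicle (113 higher, 179 lower) and 83 with LDL (38 higher, 45 lower). The vehicle count was 94, 70 and 83 without WT vehicle libraries 1, 2 and 3, and 144 and 186 without Tet2KO vehicle libraries 2 and 3. The LDL count was 38 and 17 without WT LDL libraries 1 and 2, 15 and 8 without Tet2KO LDL libraries 1 and 2, and 1, without Cd55, with only the LDL libraries fitted. With the replicate number as a block the counts were 160 and 31, although residuals gave no pairing by number.

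LDL called no gene in batch 1. Idi1 held 8.15 ± 0.198 CPM with LDL and 16.9 ± 2.60 with vehicle in WT (-1.04 ± 0.16, adjusted p = 0.232), and Abcg1 350.3 ± 63.6 and 225 ± 15.9 (0.64 ± 0.13, adjusted p = 0.35). In the cholesterol biosynthesis list 0 of 24 genes passed (13 fell adjusted over the list alone, camera adjusted p = 9.9e-16, or 0.0915 with an estimated correlation). By edgeR 0 genes passed in WT and 0 in Tet2KO, with 707 and 1126 at an unadjusted p under 0.05, while DESeq2 called 73 and 196. The interaction of Tet2KO and LDL called 0 genes by edgeR, with 236 at an unadjusted p under 0.05, and 4 by DESeq2. Of the genes called for LDL in WT of the main set, 2054 of 2532 (81.1%) had the same sign in batch 1 (fry p = 0.0262, exact permutation p = 0.1, the smallest that 10 groupings can give). The p of fry was 0.0859 without WT vehicle library 2, 0.0732 without WT vehicle library 3 and 0.185 without WT LDL library 1.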

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

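The test of the length and GC trend in the Jak2VF interaction and the 4 tests of granule transcripts were chosen after the results were seen. A difference between groups stands apart, in interaction terms sharing WT libraries. The LDL effect differed from that of WT in 84 genes in Dnmt3aKO, 20 in Tet2KO and 480 in Jak2VF. With 1 library left out the counts ran from 41 (without WT vehicle library 3) to 645 (without WT LDL library 2) in Dnmt3aKO, from 2 (without WT or Tet2KO vehicle library 2) to 41 (without Tet2KO LDL library 2) in Tet2KO, and from 91 (without Jak2VF LDL library 3) to 3600 (without WT LDL library 2) in Jak2VF. On the log2 scale the difference in Dnmt3aKO was 1.83 for Cdcp1, 1.59 for Serpinb2, 1.51 for Met, 1.07 for Nlrp3, 0.72 for Idi1, -1.32 for Ppbp, -1.76 for Angptl4 and -1.88 for Bmp4. It was -1.25 for Gprc5c, -2.04 for Ciita and 1.60 for Cdcp1 in Tet2KO, and in Jak2VF 1.65 for Cdcp1, 1.21 for Top2a, 0.87 for Ccna2, -1.52 for Angptl4, -2.05 for H2-Aa and -2.38 for H2-Eb1. With only the 12 libraries compared fitted, those of Tet2KO and all of Jak2VF but H2-Eb1 were no longer called, and with the description number as a block none of any genotype was.

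Lists called by both camera and fry follow with mean log2 difference, camera adjusted p, and that p with an estimated correlation. A list that recurs is not independent, as WT is shared. In Dnmt3aKO they were cholesterol biosynthesis (0.28, 9.3e-07, 0.183), inflammatory cytokines and NF-kB targets (0.34, 0.0029, 0.183), resident macrophage markers (-0.32, 0.0042, 0.235), hypoxia and glycolysis (-0.33, 1.2e-04, 0.235) and megakaryocyte markers (-0.64, 9.8e-04, 0.235). In Tet2KO they were cholesterol biosynthesis (0.24, 1.3e-07, 0.0597), inflammatory cytokines and NF-kB targets (0.30, 0.00198, 0.0767), cell cycle (0.39, 3.4e-16, 0.0503) and megakaryocyte markers (-0.67, 6.4e-07, 0.0597). In Jak2VF they were antigen presentation and interferon gamma targets (-0.87, 7.4e-08, 0.53), cell cycle (0.50, 2.7e-09, 0.254), hypoxia and glycolysis (-0.35, 4.3e-04, 0.436), monocyte markers (-0.47, 0.0329, 0.531), neutrophil and granule markers (-0.71, 7.7e-05, 0.254) and megakaryocyte markers (-0.93, 1.5e-04, 0.254). The camera adjusted p of monocyte markers in Jak2VF was 0.0743 without Jak2VF LDL library 2.

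Other splits of the same libraries, with only the groups compared fitted, were set beside the real one. For LDL against vehicle in WT, Dnmt3aKO, Tet2KO and Jak2VF the real split called 1261, 5542, 1472 and 2396 genes and the highest other 0 in each. Against WT, Dnmt3aKO called 2665 with vehicle (highest other 0) and 1284 with LDL (highest other 2), Tet2KO 1058 and 38 (0 and 0), Jak2VF with LDL 264 (0), and Tet2KO against Dnmt3aKO 3443 and 975 (0 and 0). In batch 1, Tet2KO against WT with vehicle called 228 (0), and recurrence of the main set effect had a fry p of 0.0196 (lowest other 0.0902). In each of these 1 of 10 splits, the real one, gave as much, and 10 splits are too few for a share under 0.05. For Jak2VF against WT with vehicle 2 of 10 did: the real split called 724, and the one that put Jak2VF libraries 1 and 2 with WT library 1 called 2604. That split points to a structure of the samples, and it follows the trend on transcript length: the slopes were -0.213, -0.132 and -0.111 in those 3 libraries and 0.0635, 0.0223 and 0.0999 in the others. With that trend removed 2801 genes differed, beside 1857 before, with all groups fitted.

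For the interactions 100 splits were drawn. In Dnmt3aKO 5 of 100 called at least the 50 genes of the real split, so chance is not excluded, and the highest other called 4247. In Tet2KO edgeR called 0 genes in the real split (934 at an unadjusted p under 0.05, and 169 by DESeq2 with all groups fitted), which 100 of 100 splits reach, and the highest other called 4186. Any split reaches a count of 0, so that share says nothing about chance. In Jak2VF 3 of 100 called at least the real 22, a share under 0.05, and the highest other called 4105. That share does not exclude chance, since the drawn splits mix genotypes within a treatment and so carry genotype differences as well. Splits with so many calls point to a structure of the samples. In Jak2VF the highest had the widest gap in length slope of the 100 (0.380, real split 0.264), and in Tet2KO the 2 highest had the 2 widest (-0.317 and -0.352), so these go with the length trend, although no split was refitted without it. In Dnmt3aKO the highest did not, with a gap of 0.157 beside 0.150 in the real split. That split kept the LDL labels and exchanged the genotype of every vehicle library. It thus added up the genotype differences under both treatments in place of testing an interaction. The same exchange called 1794 genes in Jak2VF and 842 in Tet2KO. With the length and GC trend removed and all groups fitted, the interactions called 350, 124 and 760 genes. Before removal, Spearman's rho of the log2 difference with transcript length was 0.490 in Dnmt3aKO, -0.00774 in Tet2KO and 0.630 in Jak2VF.

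The LDL response that differs between Jak2VF and WT, 480 genes but 22 when only the 12 libraries compared were fitted, was weighed against 2 technical explanations. Against a transcript length and GC trend as the whole cause, 341 of 480 genes (71.0%) stayed called once the trend was removed, although their median log2 difference, taken in its first direction, went from 0.80 to 0.65. Against a difference in depth, 370 genes (77.1%) stayed called with each library thinned to 24105237 counts, with a median of 0.81. The length trend may still account for part of the size of the effect, as the drop of that median leaves open. The Jak2 allele itself stays open as an untested biological explanation.

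Genes beside Tet2 were often among those that differ between Tet2KO and WT. Of 107 genes within 10 Mb of it 15 differed with vehicle (14.0%, elsewhere 5.43%), a ratio of 2.58 (Fisher adjusted p = 0.00683) that was 3.43 with LDL and 1.27 in Dnmt3aKO (p = 0.352). A candidate explanation is flanking DNA of another mouse strain around the floxed allele, while the window of Dnmt3a gave 0.653 in Dnmt3aKO, and that of Jak2, which holds a cluster of interferon genes, gave 1.88 in Jak2VF (adjusted p = 0.0288) but also 1.62 in Dnmt3aKO (adjusted p = 0.0938), whose allele lies elsewhere. For Rpl34, in the Tet2 window, the tables leave open that its reads were counted to pseudogenes: with vehicle Rpl34 differed by -125 CPM and its 2 pseudogenes by 151 CPM, and the sum of the 3 moved by 0.484 SD of the WT libraries. An effect of Tet2 loss on its neighbours stays open and was not tested.

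Granule protein transcripts that differ from WT were weighed as a sign of other cells in the cultures. The most abundant of the list, Mmp8, S100a9, S100a8, Mmp9 and Ltf (means of 141, 131, 98.4, 61.0 and 35.4 CPM), were all higher in Dnmt3aKO with vehicle, while in Tet2KO S100a9, S100a8 and Ltf were lower and Mmp8 and Mmp9 higher (adjusted p up to 0.114 without Tet2KO vehicle library 1 and 0.128 without library 3). A lower share of macrophages in Dnmt3aKO would raise markers of every other cell type only if those types kept their proportions. The T and NK cell list fell there (fry adjusted p = 0.00267, mean log2 fold change -0.76), which argues against such an even rise. It does not test a lower share of macrophages through more cells of a single other type. Fewer cells of the neutrophil lineage as the whole cause in Tet2KO of the main set would raise no member, yet 5 of 15 rose. That number was 2 without Tet2KO vehicle library 1 or 2, and Ctsg, Mmp8 and Mmp9 were lost without WT vehicle library 3. With these libraries left out, Mmp8 stood at 0.35 or above, while Ltf stood at -2.71 with all libraries. More cells of the neutrophil lineage in Dnmt3aKO are a candidate explanation, since 13 of 15 members rose, none of which another list holds, although the labels name no sort and these data do not show how many of them macrophages express. In batch 1, where 0 of 14 members were higher and 2 lower in Tet2KO with vehicle (list fry adjusted p = 0.0118), fewer such cells stay open, as they do for the members that fell in the main set, and so does expression of granule genes by macrophages that lack Dnmt3a or Tet2, which was not tested.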

How the results depend on the processing

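Limma, DESeq2 and its size factors, removal of the length and GC trend, the residual component, the settings that left out 2 libraries, and list tests without each library were chosen after the results had been seen. Of 3162 tests of named genes under the alternatives, 3032 kept their direction and their side of the threshold, 111 no longer passed, 19 newly passed and 0 reversed. Of those that no longer passed, 39 did so with limma on unscaled counts and 33 with a library left out. A further 18 did so with the description number as a block and 14 in a fit of only the groups compared. Of 241 list calls, 75 held with an estimated correlation and 230 to 249 calls were made without 1 library. Counts stayed within 1.5 times of those reported with DESeq2 size factors in edgeR and with quantile normalization, for the 20 and 25 results run under each. The counts that follow moved by more than 1.5 times, and the cause was not tested. A block, a left-out library or a fit of only the groups compared leaves fewer libraries or residual degrees of freedom. That alone does not account for counts that rose. With only the groups compared fitted, LDL in Dnmt3aKO went from 2988 to 5542. Without WT LDL library 2 the Jak2VF interaction went from 480 to 3600. Genes with low counts or a change of 1.5-fold can be missed, as 29.9% of simulated changes of that size were recovered. Depth was not varied in that simulation.

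In numbers of genes called, DESeq2 gave 458, 169 and 1807 for the interaction of LDL with Dnmt3aKO, Tet2KO and Jak2VF, 73 and 196 for LDL in WT and Tet2KO of batch 1, 693 and 406 for Tet2KO of batch 1 with vehicle and LDL, and 4 for the interaction in batch 1. A test with no filter on low counts gave 208, 36 and 1963 for the interaction of LDL with Dnmt3aKO, Tet2KO and Jak2VF, 3 for LDL in Tet2KO of batch 1, and 136 for Tet2KO of batch 1 with LDL. A pseudocount of 5 gave 139 for Tet2KO of batch 1 with LDL, and limma on scaled counts gave 129 for Tet2KO of batch 1 with LDL. A fit of only the groups compared gave 1261, 5542 and 1472 for LDL in WT, Dnmt3aKO and Tet2KO, 724 for Jak2VF against WT with vehicle, and 1284, 38 and 264 for Dnmt3aKO, Tet2KO and Jak2VF against WT with LDL. Such a fit also gave 3443 and 975 between the knockouts with vehicle and LDL, 50, 0 and 22 for the interaction of LDL with Dnmt3aKO, Tet2KO and Jak2VF, and 1 for Tet2KO of batch 1 with LDL. Removal of the length and GC trend gave 3245, 1676 and 2801 for Dnmt3aKO, Tet2KO and Jak2VF against WT with vehicle, and 864 for Tet2KO against WT with LDL. This also gave 350, 124 and 760 for the interaction of LDL with Dnmt3aKO, Tet2KO and Jak2VF, 1 and 15 for LDL in WT and Tet2KO of batch 1, 519 and 213 for Tet2KO of batch 1 with vehicle and LDL, and 1 for the interaction in batch 1. A covariate for the first residual component, which takes up within-group spread chosen from the same data and leaves 15 residual degrees of freedom in place of 16, gave 6553, 5939, 6983 and 8004 for LDL in WT, Dnmt3aKO, Tet2KO and Jak2VF, 4362, 4142 and 5551 for Dnmt3aKO, Tet2KO and Jak2VF against WT with vehicle, and 8327, 2859 and 7428 for Dnmt3aKO, Tet2KO and Jak2VF against WT with LDL. The same covariate gave 4232 and 5679 between the knockouts with vehicle and LDL, 4070, 507 and 6965 for the interaction of LDL with Dnmt3aKO, Tet2KO and Jak2VF, 13 and 101 for LDL in WT and Tet2KO of batch 1, and 1340 and 1210 for Tet2KO of batch 1 with vehicle and LDL. Without the 2 libraries with brain transcripts the counts were 2037, 289 and 1184 for Dnmt3aKO, Tet2KO and Jak2VF against WT with LDL, and 0 and 229 for the interaction of LDL with Tet2KO and Jak2VF, and without the 2 with high stromal transcripts 44 for Tet2KO of batch 1 with LDL.

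Limma on unscaled counts gave 1124, 1257 and 1071 for LDL in WT, Tet2KO and Jak2VF, 822, 240 and 342 for Dnmt3aKO, Tet2KO and Jak2VF against WT with vehicle, and 1232, 157 and 545 for Dnmt3aKO, Tet2KO and Jak2VF against WT with LDL. It also gave 913 and 840 between the knockouts with vehicle and LDL, 14, 1 and 3 for the interaction of LDL with Dnmt3aKO, Tet2KO and Jak2VF, and 2 and 7 for LDL in WT and Tet2KO of batch 1. Lack of scaling shifted the median log2 fold change of all genes, and with it the share of called genes that were higher. For LDL the shift was -0.11 in WT, -0.39 in Dnmt3aKO and -0.11 in Tet2KO, and 31.9%, 7.53% and 31.4% of calls were higher in place of 46.8%, 41.7% and 51.1%. Against WT with vehicle it was 0.13 in Dnmt3aKO, -0.14 in Tet2KO and 0.09 in Jak2VF, with 73.5%, 43.3% and 78.4% higher in place of 50.3%, 50.4% and 45.0%. Against WT with LDL it was -0.16, -0.11 and 0.17, with 30.4%, 21.7% and 86.4% in place of 45.8%, 46.4% and 42.3%. Between the knockouts with vehicle the shift was -0.26 and 21.6% were higher in place of 46.5%, and in the Dnmt3aKO interaction it was -0.29, with 7.14% in place of 44.0%. In batch 1 it was 0.40 for LDL in WT, -0.16 for LDL in Tet2KO and 0.55 for Tet2KO with vehicle, where 90.3% were higher in place of 38.7%, while Tet2KO with LDL went from 45.8% to 60.9%. In the Tet2KO interaction 40% of calls had a higher effect, 27.6% with quantile normalization, 52.7% with DESeq2 and 100% without scaling.

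With the title number as a replicate block the counts that moved were 133 and 40 for the interaction of LDL with Dnmt3aKO and Tet2KO, and 160 and 31 for Tet2KO of batch 1 with vehicle and LDL. As a block within genotype it gave 8 and 1549 for the interaction of LDL with Tet2KO and Jak2VF, and 27 for LDL in Tet2KO of batch 1. The description number as a block within genotype, which leaves 4 residual degrees of freedom, gave 597, 867, 712 and 543 for LDL in WT, Dnmt3aKO, Tet2KO and Jak2VF, and 0, 0 and 0 for the interaction of LDL with Dnmt3aKO, Tet2KO and Jak2VF. The 3 counts of 0 come from edgeR, with 724, 521 and 1094 genes at an unadjusted p under 0.05, where the count of 0 in Tet2KO had 934 when only the groups compared were fitted and 1220 without the brain transcript libraries. A block moved no other count by that much.

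Leaving out 1 library at a time gave ranges of 1867 to 3930, 2278 to 2403, 2318 to 4088 and 2028 to 5027 for LDL in WT, Dnmt3aKO, Tet2KO and Jak2VF, 1561 to 1839, 644 to 833 and 1005 to 2069 for Dnmt3aKO, Tet2KO and Jak2VF against WT with vehicle, and 1842 to 5795, 361 to 814 and 631 to 4492 for Dnmt3aKO, Tet2KO and Jak2VF against WT with LDL. It gave 1228 to 1296 and 1500 to 3034 between the knockouts with vehicle and LDL, and 41 to 645, 2 to 41 and 91 to 3600 for the interaction of LDL with Dnmt3aKO, Tet2KO and Jak2VF. It also gave 0 and 0 for LDL in WT and Tet2KO of batch 1, 70 to 249 and 8 to 38 for Tet2KO of batch 1 with vehicle and LDL, and 0 for the interaction in batch 1. The counts of 0 are by edgeR, with 707, 1126 and 236 genes at an unadjusted p under 0.05 when every library was kept. In batch 1 a group of 2 then holds 1 library, which is assumed to vary like the other groups. The p of fry ran from 0.00181 to 0.0249 for Tet2KO with vehicle, 1.1e-04 to 3.5e-04 for Tet2KO with LDL and 0.0206 to 0.185 for LDL in WT. The r of Dnmt3aKO and Tet2KO effects ran from 0.353 to 0.447 with vehicle and 0.247 to 0.591 with LDL, and with Tet2KO effects from batch 1 it was -0.157 and -0.128. For Jak2VF and Tet2KO effects it ran from 0.126 to 0.333 with vehicle and 0.321 to 0.652 with LDL. The camera adjusted p of lists that changed direction without 1 library ran from 6.2e-12 to 0.895 for interferon response and 1.0e-04 to 0.348 for antigen presentation in Tet2KO with LDL (both without WT LDL library 1). In the interaction of batch 1 it ran from 9.7e-16 to 0.823 for interferon response, 3.2e-07 to 0.841 for cell cycle, 5.1e-05 to 0.996 for hypoxia and 1.3e-04 to 0.996 for imprinted genes. A covariate for sex was not run, as no library held Xist at a female level.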

Other observations

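The comparisons without the 2 libraries that hold brain transcripts, and without the 2 of batch 1 with high stromal transcripts, were chosen after the values were seen. In WT macrophages LDL moved genes of alternative activation both ways: Arg1, an arginase, rose from 329 ± 91.6 to 1835 ± 273 CPM (2.50 ± 0.20) while Mrc1, a mannose receptor, fell by 1.53 ± 0.19. In that list 4 of 12 fell, 2 rose and 6 did not pass (6 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.292, or 0.408 with an estimated correlation). Among STAT5 and cytokine feedback targets 5 of 15 rose and 10 did not pass (5 rose adjusted over the list alone, camera adjusted p = 8.6e-04, or 0.05 with an estimated correlation), with Pim1, a kinase, at 0.99 ± 0.09 and Socs3, a suppressor of cytokine signals, at 0.72 ± 0.10. In the lysosome list 3 of 21 rose, 2 fell and 16 did not pass (3 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.475, or 0.854 with an estimated correlation), with Ctsl, a protease, at 0.94 ± 0.11. In the ER stress and amino acid list 4 of 18 rose, 1 fell and 13 did not pass (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0745, or 0.454 with an estimated correlation), with Ddit4, an inhibitor of mTOR, at 1.31 ± 0.13.

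Further lists were tested between genotypes with vehicle. In the DNA methylation machinery of Dnmt3aKO 3 of 13 fell, 1 rose and 9 did not pass (4 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.169, or 0.351 with an estimated correlation), with Uhrf1, which guides maintenance methylation, at -0.69 ± 0.13 and Tdg, a glycosylase, at -0.63 ± 0.09. Dendritic cell markers were higher in Tet2KO (2 of 9 rose and 7 did not pass (3 rose adjusted over the list alone, camera adjusted p = 0.0056, or 0.027 with an estimated correlation)), Flt3, a cytokine receptor, by 1.59 ± 0.35 (adjusted p = 0.0527 without WT vehicle library 2). Megakaryocyte markers were higher in Tet2KO as well (4 of 10 rose and 6 did not pass (7 rose adjusted over the list alone, camera adjusted p = 3.7e-07, or 0.027 with an estimated correlation)), with Itga2b at 0.95 ± 0.20. In Jak2VF, of erythroid markers 3 of 6 rose and 3 did not pass (4 rose adjusted over the list alone, camera adjusted p = 0.01, or 0.195 with an estimated correlation), with Hba-a1, a globin, at 2.04 ± 0.43. That camera adjusted p was 0.09 without Jak2VF vehicle library 3. Of stromal markers 4 of 11 rose and 7 did not pass (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.7e-05, or 0.145 with an estimated correlation), with Dcn, a proteoglycan, at 0.66 ± 0.13.

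Sex-linked and mitochondrial transcripts were read in each library. Xist did not exceed 0.318 CPM in the main set, where Ddx3y held 44.0 to 127 CPM. Of sex-linked genes in Dnmt3aKO with LDL 2 of 5 rose and 3 did not pass (4 rose adjusted over the list alone, camera adjusted p = 0.00954, or 0.261 with an estimated correlation), with Eif2s3y at 0.64 ± 0.10. Mitochondrial transcripts were tested in batch 1 alone, where with Tet2KO and vehicle 0 of 13 genes passed (0 passed adjusted over the list alone, camera adjusted p = 5.0e-04, or 0.358 with an estimated correlation). The germline list held fewer than 5 tested genes in each set and had no test.

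Some libraries held more of a transcript typical of another tissue than others of their group. Gfap was at 4.25 CPM in Tet2KO LDL library 3 and 2.67 in WT LDL library 3, and without these 2 libraries 289 genes differed between Tet2KO and WT with LDL, beside 537. Col1a1 was not limited to single libraries of the main set, where each library held 2360.4 to 6235 CPM. Each of these lay above the 2 libraries of batch 1 left out for high stromal transcripts. Those held 1536 CPM (Tet2KO vehicle library 3) and 1490.3 CPM (Tet2KO LDL library 2), beside 143 to 276 in WT with vehicle of batch 1.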
